A study of Mus musculus with 13 samples.

How the data were processed

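Messenger RNA of mouse brain tissue was sequenced in 13 libraries of 4 groups: flox controls in normoxia (n = 3), knockouts in normoxia (n = 3), flox controls in hypoxia (n = 3) and knockouts in hypoxia (n = 4). The knockout (KO) lacks Pdcd10, also called Ccm3, in brain endothelial cells through a tamoxifen-inducible Cre recombinase under the Slco1c1 promoter, and the controls (flox) carry the loxP-flanked gene without that Cre, per the labels. Libraries came from 50 ng of RNA with an integrity number above 8.0 and a stranded mRNA kit, per the series' design text. Groups and replicate numbers were taken from the sample titles.

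The authors deposited a table of raw counts per gene and a table of RPKM values for the same 55416 Ensembl gene identifiers. HISAT2, edgeR and the GRCm39 build are named in the submitters' processing notes, without versions or roles, and the strand setting and gene annotation of the counting are not given in the sources used here. The deposited RPKM values equal the deposited counts divided by the column total and by 1 length per gene, with a relative range of that length of at most 9.8e-15 over the 35248 genes with a count in at least 2 libraries, so they carry no composition factor. The reference at hand is another build than the authors', so gene coordinates are not given and it served only for names and for which genes lie side by side. Of the identifiers, 52083 had a symbol in the name table and 3333 had none. Those without held 0.346% of counts.

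Total counts ran from 42090437 to 71216636 per library, at which 3 counts, the most that a count of 0 allows, come to between 0.0421 and 0.0713 CPM. This floor covers counting error only. The chi-square per degree of freedom between libraries of 1 group, over genes with at least 20 counts in the pair, was at least 4.45, so no library repeated another. The labels describe tissue taken from animals, without an animal identifier, and p-values measure the spread between these libraries. No batch or date is given in the labels.

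Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr over the 4 groups, which left 22507 genes holding at least 99.95% of each library's counts, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 13 libraries (common dispersion 0.00967), and 5 contrasts were tested: KO against flox in normoxia and in hypoxia, hypoxia against normoxia in flox and in KO, and the difference between the effects (the interaction). P-values were adjusted by Benjamini and Hochberg's method over the genes of 1 contrast, with a threshold of 0.05. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic. CPM values are scaled by TMM.

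Before the data were examined, 45 gene lists (pathways, cell types, brain regions and sex-linked genes) were fixed, of which 44 were tested and the sex-linked list was only inspected. Some lists share genes, so their results are not independent of one another. The list test was limma's camera (version 3.58.1) with a preset correlation of 0.01 for lists with at least 5 genes tested, and it was repeated with a correlation estimated per list and with fry. The genes named were also fixed by rule. Per pairwise contrast these were the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 2 log2 CPM and no overlap between the groups' libraries, leaving out predicted, unnamed and sex-linked genes. To these were added up to 4 members of each list that passed the list test or held at least 3 genes past the threshold, up to 2 members that did not pass, and 10 genes named in every contrast. The 5 largest of each direction were to be named for the interaction, where no gene passed. Values of some single genes that meet these rules are not reported here, although counts of genes include them.

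The share of counts from hemoglobin genes, from mitochondrially encoded genes and from the 50 most abundant genes was compared by two-sided exact permutation tests. Alternatives fixed beforehand were RLE scaling, no composition factor, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), a replicate block, a minimum fold of 1.5, fits of only the libraries compared and leaving out each library. A sex term and a fit to the 9 libraries with Y-linked transcripts were added after the data were seen.

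The tests were tested on simulated data, counts for the 22507 genes in which 200 were changed. The changed genes were drawn only from those above a minimum expected count, and genes were simulated independently, with no library standing apart. The shares called may thus be lower for genes with few counts or where 1 library stands apart. For KO against flox in normoxia, edgeR called 82.1% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold, with 7 unchanged genes called. For hypoxia against normoxia in flox the shares were 73.1%, 92.5% and 100%.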

Results

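Gene expression was measured by RNA sequencing in brain tissue of mice with or without Pdcd10 in brain endothelial cells, kept in normoxia (21% oxygen) or in hypoxia (12% oxygen for 7 days). Loss of Pdcd10, also known as Ccm3, in endothelium is a model of cerebral cavernous malformation, a disease of leaky, enlarged brain capillaries. The knockouts (KO) had received 50 µg of 4-hydroxytamoxifen on postnatal day 1, per the series' design text, and were compared with littermates carrying the floxed gene without Cre recombinase (flox). That text leaves open whether the flox mice were injected too. There were 3 flox and 3 KO libraries in normoxia and 3 flox and 4 KO libraries in hypoxia, with between 42090437 and 71216636 counts each. On the first dimension of a multidimensional scaling plot, which held 27.9% of the variance, each flox library lay below 0 and each KO library above 0.

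**Figure D1:**
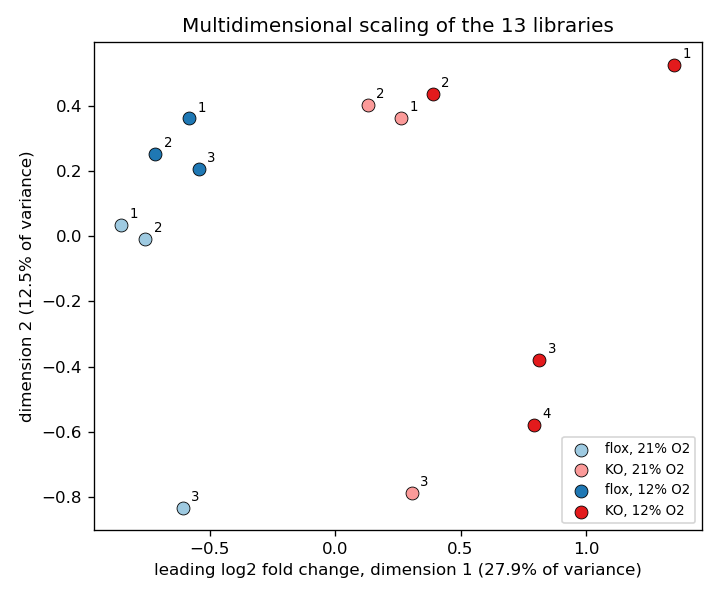
Multidimensional scaling of the 13 libraries, with axes in leading log2 fold change, colours for the 4 groups and numbers for the replicates. The 6 flox libraries lie on the left of dimension 1 and the 7 KO libraries on the right, with KO hypoxia replicate 1 farthest right at 1.352, and the second dimension parts replicate 3 of both normoxia groups and replicates 3 and 4 of the KO hypoxia group from the rest. The libraries parted by the second dimension are those with the X-inactivation transcript Xist and almost no Y-linked transcripts.

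Pdcd10 itself (ENSMUSG00000027835) did not differ detectably between genotypes in whole tissue. Its level was 17.1 ± 0.799 CPM in flox and 16.9 ± 1.07 CPM in KO in normoxia (SD, n = 3 each), and 17.4 ± 0.194 CPM in flox (n = 3) and 16.4 ± 1.09 CPM in KO (n = 4) in hypoxia. The log2 fold changes were -0.02 ± 0.07 in normoxia and -0.09 ± 0.07 in hypoxia (SE, edgeR adjusted p = 0.962 and 0.47). In hypoxia each of the 4 KO libraries lay below each of the 3 flox libraries. The deletion is restricted to brain endothelial cells, so the level in whole tissue does not check the genotype labels. Slco1c1, whose promoter drives the Cre, was also not called between genotypes, at 0.34 ± 0.29 in normoxia and -0.28 ± 0.27 in hypoxia.

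The first question was what differed between KO and flox in normoxia. Each KO library comes from an injected mouse with the Cre transgene. Effects of loss of Pdcd10, of the transgene and possibly of the injection thus cannot be told apart, here or in hypoxia. Of 22507 genes tested, 524 passed the threshold, 441 higher and 83 lower in KO. Endothelial transcripts rose as a group: 17 of 18 pan-endothelial markers passed, none fell, and their median log2 fold change was 0.996. Cldn5, a tight junction protein, went from 21.0 ± 3.45 to 60.2 ± 4.27 CPM (SD, n = 3 each; log2 fold change 1.52 ± 0.14), and Vwf, the von Willebrand factor, rose by a log2 fold change of 1.84 ± 0.30. Of 14 genes of the KLF2 and KLF4 axis, 6 rose and none fell. Among them were the transcription factors Klf4 (1.45 ± 0.25) and Klf2 (1.03 ± 0.24), the anticoagulant receptor Thbd (1.42 ± 0.16) and the endothelial nitric oxide synthase Nos3 (1.44 ± 0.13). Adamts4, an aggrecan-cleaving protease of the same list, had a log2 fold change of -0.50 ± 0.15 and was not called (edgeR adjusted p = 0.122).

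The blood-brain barrier list had 13 of 20 genes higher, with Pglyrp1 at 2.08 ± 0.19 and the amino acid transporter Slc38a5 at 1.26 ± 0.10. Tip cell and sprouting genes had 12 of 28 higher, including Aplnr (2.87 ± 0.34), Kdr (1.11 ± 0.12) and Robo4 (1.08 ± 0.13). Set against the pan-endothelial score of the same library (mean log2 CPM), a measure chosen after the values were seen, both were lower in KO, at 0.60 against 1.07 in flox for the barrier and -1.31 against -0.74 for tip cells (exact p = 0.1 each, the smallest that 3 against 3 allow). A list gene that does not rise with the endothelial markers lowers this score in KO, such as Nrp2 of the tip cell list (56.0 CPM in flox, 51.3 in KO). The score thus cannot show whether endothelial cells themselves held fewer of these transcripts. Pericyte markers had 7 of 12 higher, with Rgs5 at 0.97 ± 0.09 and Vtn at 1.00 ± 0.10. Of 19 genes of endothelial-to-mesenchymal transition 7 rose, among them Fn1, which encodes fibronectin (1.46 ± 0.17), and Ly6a (1.80 ± 0.24). Ly6a is also in the pan-endothelial list, and Vim of the mesenchymal list is also in that of reactive astrocytes. The rise in whole tissue thus does not show a transition of endothelial cells. In the coagulation list 6 of 17 rose, and in the TGF-beta and BMP list 7 of 20 rose, such as Acvrl1 (1.25 ± 0.15).

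Of 30 genes of reactive astrocytes 13 rose, with Gfap, the astrocyte intermediate filament, going from 440 ± 34.4 to 1188 ± 34 CPM and Vim at 1.47 ± 0.16. Interferon response genes had 9 of 22 higher, including Ifitm3 (1.26 ± 0.14) and Gbp3 (1.15 ± 0.14), and antigen presentation genes had 6 of 15 higher, including Cd74 (1.61 ± 0.27). In the list of T and B lymphocytes 2 of 11 were called higher. There Cd79b was at 0.155 CPM in flox and 0.552 in KO and Igkc at 0.495 and 1.34, while Ighm was at 16.4 and 21.5. Microglial genes were mostly not called, with 0 of 16 homeostatic and 1 of 22 disease-associated genes higher, and these lists were at adjusted p = 0.14 and 0.2 with an estimated correlation. Erythroid genes had 5 of 9 called higher. Hba-a1, an alpha globin, went from 45.8 ± 10.9 to 435 ± 122 CPM. That list lost its call with an estimated correlation (adjusted p = 0.075). The lower genes included Dsp (-0.97 ± 0.14), C1ql2 (-0.79 ± 0.10) and Prox1 (-0.63 ± 0.10). Of 16 myelin and oligodendrocyte genes 2 passed, Myrf (-0.33 ± 0.08) and Mag (-0.40 ± 0.10), and 15 were lower when adjusted over the list alone, with adjusted p = 0.1 with an estimated correlation.

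Of the 44 lists, 28 passed camera with the preset correlation, and 12 of them held with an estimated correlation: those of endothelium, barrier, KLF2 and KLF4, tip cells, mesenchymal transition, pericytes, coagulation, TGF-beta, reactive astrocytes, interferon, antigen presentation and lymphocytes. Adjusted over the list alone, 18 pan-endothelial, 14 barrier, 16 tip cell, 19 reactive astrocyte and 20 interferon genes were higher. Xist, the X-inactivation transcript, was present in 1 library of each normoxia group and 2 of the KO hypoxia group, although each library is labelled male. The count of 524 genes was 250 without flox normoxia replicate 1, 260 without KO normoxia replicate 1 and 299 without KO normoxia replicate 2. It was 311 in the 9 libraries with Y-linked transcripts.

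**Figure D2:**
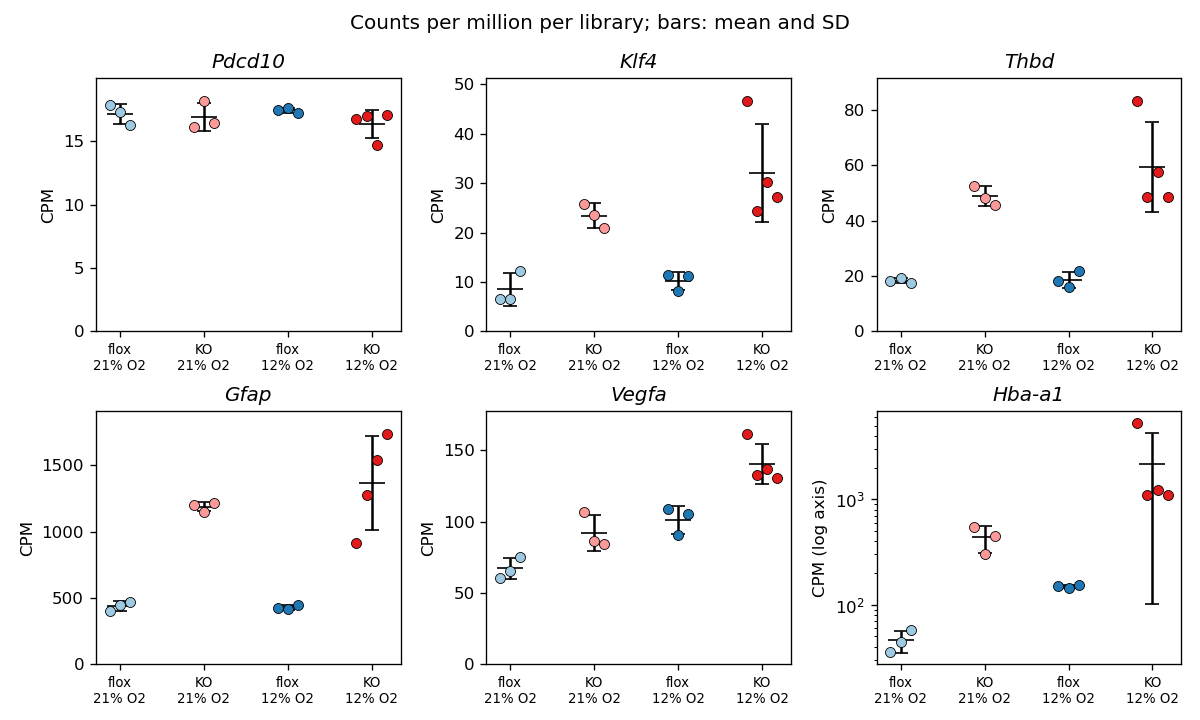
CPM of 6 genes in each library (points) by group, with the mean and SD as bars; the Hba-a1 axis is logarithmic. Pdcd10 overlaps between genotypes in normoxia, and in hypoxia each KO library (at most 17.03 CPM) lies just below each flox library (at least 17.2 CPM), while Thbd, Klf4, Gfap and Hba-a1 are higher in every KO library than in the flox libraries at the same oxygen level, and KO hypoxia replicate 1 is the highest for Hba-a1 at 5305 CPM.

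In hypoxia, KO differed from flox in 2039 genes, 1526 higher and 513 lower. All 18 pan-endothelial markers passed as higher (median log2 fold change 1.083), with Pecam1 at 1.47 ± 0.14 and Esam at 1.03 ± 0.10. Of the KLF2 and KLF4 axis 10 of 14 rose, with Klf4 at 1.65 ± 0.24, Klf2 at 1.10 ± 0.22, Thbd at 1.68 ± 0.16 and Nos3 at 1.51 ± 0.12, while Adamts4 was at -0.21 ± 0.14 and was not called. Tip cell genes had 18 of 28 higher, among them the vessel-destabilising ligand Angpt2 (1.55 ± 0.19) and Apln (1.17 ± 0.14). The barrier list had 14 of 20 higher, and pericytes 9 of 12 higher and 1 lower. Without KO hypoxia replicate 1, 18 pan-endothelial, 9 KLF2 and KLF4, 16 tip cell, 13 barrier and 9 pericyte genes were called higher and 0 pericyte genes lower. The medians were then 0.954 in place of 1.083 for pan-endothelial markers and 0.58 in place of 0.732 for pericytes. With all libraries, barrier and tip cell genes were lower in KO by 0.59 and 0.43 relative to the pan-endothelial score (exact permutation test, adjusted p = 0.114 each), with the same limit as in normoxia. Vegfa, the main angiogenic growth factor, was at 101 ± 9.77 CPM in flox (n = 3) and 140 ± 14.2 CPM in KO (n = 4), a log2 fold change of 0.47 ± 0.10.

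Reactive astrocyte genes had 25 of 30 higher, including Vim (2.04 ± 0.16), Gfap (1.67 ± 0.15), the oncostatin M receptor Osmr (1.38 ± 0.12) and Emp1 (2.55 ± 0.29). Of 31 extracellular matrix genes 22 rose, with Fn1 at 2.01 ± 0.17, Col3a1 at 2.36 ± 0.24 and Lama5 at 1.35 ± 0.12. Interferon response genes had 19 of 22 higher and antigen presentation genes 13 of 15, with H2-Ab1 at 2.47 ± 0.33 and B2m at 0.84 ± 0.10. Microglial genes rose: 13 of 16 homeostatic genes, including Csf1r (0.48 ± 0.07) and Cx3cr1 (0.43 ± 0.09), and 15 of 22 disease-associated genes, including Lyz2 (2.18 ± 0.28). Cytokine and adhesion genes had 16 of 31 higher, with Icam1 at 1.64 ± 0.21, while Cx3cl1, the ligand of Cx3cr1, was at -0.16 ± 0.07 and was not called (edgeR adjusted p = 0.136). Complement genes had 12 of 15 higher and 1 lower, with C4b at 1.64 ± 0.16; that list was at adjusted p = 0.052 with an estimated correlation. KO hypoxia replicate 1 stood apart as the highest of its group for Osmr, Emp1, Lyz2 and H2-Ab1. Without it the medians were 0.993 in place of 1.242 for reactive astrocytes, 0.718 in place of 0.936 for matrix, 0.958 in place of 1.047 for interferon, 1.176 in place of 1.23 for antigen presentation and 0.515 in place of 0.613 for disease-associated microglia, with 22, 21, 15, 11 and 12 genes called higher. They were 0.391 in place of 0.426 for homeostatic microglia, 0.735 in place of 0.979 for cytokines and 0.714 in place of 1.014 for complement, with 9, 12 and 10 called higher.

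All 9 erythroid genes were called higher, with Hba-a1 at 3.87 ± 0.51, and the list was at adjusted p = 0.053 with an estimated correlation. Without KO hypoxia replicate 1, 7 were called higher, and the median of the list was 2.638 in place of 3.627. Hemoglobin genes held 0.707 ± 0.674% of counts in KO hypoxia (n = 4; 0.371 ± 0.0415% without replicate 1, n = 3), 0.0523 ± 0.0119% in flox hypoxia, 0.133 ± 0.0367% in KO normoxia and 0.0196 ± 0.00594% in flox normoxia (SD, n = 3 each). Each KO hypoxia library (0.345% to 1.717%) lay above each flox hypoxia library (0.0439% to 0.0659%), and the same held in normoxia (0.0949% to 0.168% against 0.0136% to 0.0255%). The tests compared means, and replicate 1 alone held 1.717%. None of the 12 exact permutation tests of hemoglobin, mitochondrial and top-50 shares passed the threshold. The exact two-sided p for hemoglobin was 0.1 in normoxia, the smallest that 3 against 3 allow, and 0.114 in hypoxia, with adjusted p = 0.274 for each.

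Of 18 synaptic genes 4 fell, among them Shank1 (-0.26 ± 0.05) and Dlg4 (-0.17 ± 0.04). Of 13 glutamatergic genes 3 fell, such as Camk2a (-0.16 ± 0.04), and of 11 striatal genes 5 fell, such as Pde10a (-0.62 ± 0.13) and Ppp1r1b (-0.59 ± 0.14). With an estimated correlation these lists were at adjusted p = 0.054, 0.086 and 0.16. Of 13 GABAergic genes none was called. Ppp1r1b was at 84.8 ± 15.9 CPM in flox and 78.1 ± 4.89 in KO in normoxia (n = 3 each), and at 136 ± 30.5 in flox (n = 3) and 90.5 ± 10.5 in KO (n = 4) in hypoxia, so flox hypoxia was the group with the highest level. The largest falls by rule also included Fzd2 (-0.84 ± 0.10), Scn4b (-0.82 ± 0.18) and Hsd11b1 (-0.67 ± 0.08). Of the 44 lists, 34 passed with the preset correlation and 16 with an estimated one. Adjusted over the list alone, 27 reactive astrocyte, 24 matrix, 21 interferon, 21 tip cell and 14 antigen presentation genes were higher, and 11 synaptic and 9 striatal genes were lower. Without a composition factor the split was 1746 higher and 243 lower, 87.8% higher against 74.8%. The count was 1254 without flox hypoxia replicate 1 and 1151 without flox hypoxia replicate 2, and 1401 in the 9 libraries with Y-linked transcripts. With a sex term 1240 of the 1526 higher and 229 of the 513 lower calls were kept.

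**Figure D3:**
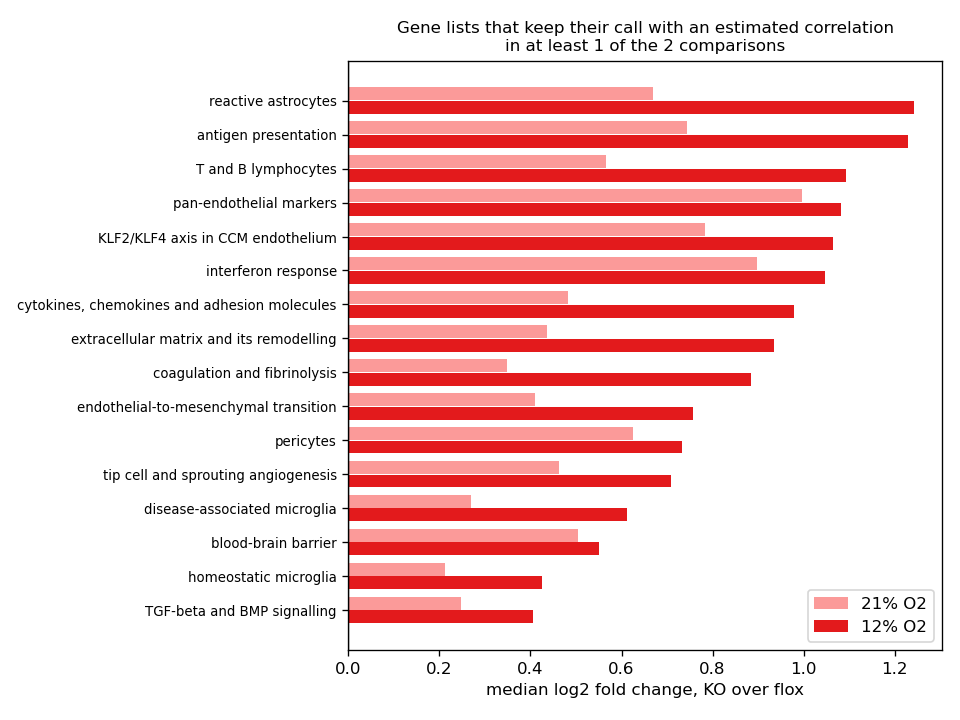
Median log2 fold change of KO over flox in 21% oxygen (light) and 12% oxygen (dark) for the 16 gene lists that kept their call with an estimated correlation in at least 1 of these comparisons. Each bar lies above 0, and reactive astrocytes reach 0.67 in normoxia and 1.242 in hypoxia.

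The knockout effects in normoxia and hypoxia, which share no library, had a Pearson r of 0.536 and a Spearman rho of 0.382 across 22507 genes; genes are not independent replicates. Called in both were 414 higher genes, where independent lists would share 29.9, and 29 lower genes, where they would share 1.89, and no gene was called in opposite directions. Both contrasts use the same model and dispersions, so genes with little spread are more readily called in both. The numbers for independent lists may thus be too low. The interaction, which tests whether the knockout effect differs with oxygen, called 0 genes by edgeR, with 1635 genes at an unadjusted p under 0.05. DESeq2 called 8 genes and limma on log2(RPKM + 1) called 2. Of the genes named in every contrast, Gfap was at 0.24 ± 0.20, Klf4 at 0.19 ± 0.33 and Vegfa at 0.01 ± 0.14 for the interaction. By camera with the preset correlation 26 lists passed, 21 up and 5 down, and none passed with an estimated correlation, where the smallest adjusted p was 0.34.

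Hypoxia against normoxia in flox mice asks what 12% oxygen changed without the deletion. Only 5 genes passed, all higher: Btg2 (1.71 ± 0.25), an antiproliferative immediate early gene, the VEGF receptor Kdr (0.84 ± 0.12), the chemokine Cxcl12 (0.60 ± 0.09), Gh and Vil1. Gh and Vil1 lie outside the naming rule and were chosen after their values were seen. Gh, growth hormone, had no count in flox normoxia and a mean of 0.875 CPM in flox hypoxia, at least 52.2-fold higher against a floor of 3 counts over the group. Prl, another pituitary hormone and also chosen after its values were seen, had 38 counts in flox hypoxia, 2 in flox normoxia and 0 in both KO groups. Gh had 121 counts in flox hypoxia, 0 in KO normoxia and 4 in KO hypoxia, so the rise of these hormones was seen in the flox hypoxia group only. Whether the tissue taken differed between groups was not tested. At an unadjusted p under 0.05 there were 1497 genes, and DESeq2 called 67. Vegfa was at 0.59 ± 0.11 and was not called (edgeR adjusted p = 0.111). With the preset correlation 18 lists passed, among them pan-endothelial markers (median 0.418), immediate early genes (0.676) and striatum (0.593). With an estimated correlation none passed, with adjusted p = 0.13 for pan-endothelial markers, 0.19 for immediate early genes and 0.13 for striatum. The median of immediate early genes was 1.347 without flox normoxia replicate 3, and that of striatum 0.823 without flox hypoxia replicate 3. The count fell to 0 without flox normoxia replicate 1, flox normoxia replicate 2 or flox hypoxia replicate 1, was 1 without flox hypoxia replicate 2 and rose to 45 without flox normoxia replicate 3, and 66 genes were called in the libraries with Y-linked transcripts.

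In KO mice, 202 genes differed between hypoxia and normoxia, 140 higher and 62 lower. Set against the 5 genes in flox, this does not show a larger effect in KO, as the interaction called 0 genes by edgeR. Tip cell genes had 10 of 28 higher, with Angpt2 at 1.71 ± 0.19, Robo4 at 0.84 ± 0.12 and Apln at 0.91 ± 0.14. Pan-endothelial markers had 8 of 18 higher, including Pecam1 (0.83 ± 0.14) and Flt1 (0.58 ± 0.10). Vegfa rose from 92.3 ± 12.6 (n = 3) to 140 ± 14.2 CPM (n = 4), a log2 fold change of 0.60 ± 0.10, and was the 1 called gene of 30 targets of the hypoxia-inducible factor. Matrix genes had 6 of 31 higher, such as Sparc (0.61 ± 0.09) and Col4a1 (0.72 ± 0.13), and pericyte genes 3 of 12, such as Ndufa4l2 (1.06 ± 0.21). Without KO hypoxia replicate 1 there were 8 tip cell, 6 pan-endothelial, 6 matrix and 1 pericyte genes higher, and the medians were 0.392 in place of 0.501, 0.426 in place of 0.566, 0.241 in place of 0.438 and 0.304 in place of 0.425. Erythroid genes had 4 of 9 higher, with Hba-a1 at 2.33 ± 0.47, and the median of the list was 2.329, or 1.321 without KO hypoxia replicate 1. Hba-a1 was at 2184 ± 2080 CPM in KO hypoxia (n = 4) and at 1143 ± 73.9 CPM without that library (n = 3). A2m (1.55 ± 0.19), the inflammatory transcription factor Cebpd (1.39 ± 0.23) and Btg2 (1.39 ± 0.24) were among the largest rises. The largest falls included Inhba (-0.78 ± 0.15), Tnnc1 (-0.64 ± 0.13), Nptx2 (-0.61 ± 0.12) and the clock gene Arntl (-0.42 ± 0.08).

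Adjusted over the list alone, 19 tip cell, 16 pan-endothelial, 13 matrix, 10 pericyte and 14 hypoxia-inducible factor target genes were higher. By the preset correlation 35 lists passed in KO mice, and none with an estimated one, with adjusted p = 0.11 for tip cells, 0.11 for pan-endothelial markers, 0.14 for matrix, 0.13 for pericytes, 0.14 for erythroid genes and 0.14 for the hypoxia-inducible factor targets. The hypoxia effects in flox and KO had a Pearson r of 0.199 and a Spearman rho of 0.12 across genes, and 4 genes were called higher in both, where independent lists would share 0.0311. That number may be too low, as for the knockout effects. Without a composition factor the split was 214 higher and 31 lower, 87.3% higher against 69.3%. The count of 202 was 25, 2 and 8 without KO normoxia replicates 1, 2 and 3, and 102, 463 and 114 without KO hypoxia replicates 1, 2 and 3, and 94 in the libraries with Y-linked transcripts.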

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

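Outliers were sought by a rule fixed before the data were examined, while the tests of explanations and the counts over other splits of the libraries were written after the values they bear on had been seen.

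Hemoglobin genes held 1.717% of counts in KO hypoxia replicate 1, far from the other 3 libraries of its group. Of 179 named genes, 28 (15.6%) had 1 library of the 4 far from the others, and in 24 of these it was replicate 1, as the highest. The rule's rate of about 1 in 20 by chance assumes independent, normally distributed values. The named genes were selected and many rise together, so that rate is no expectation here and the flags largely count the same library again. Its erythroid values were 5305 CPM for Hba-a1, 4387 for Hba-a2, 4814 for Hbb-bs, 2696 for Hbb-bt and 190.5 for Alas2. Its iron and heme values were 32.88 CPM for Hmox1 and 59.06 for Ftl1. Vascular and mural genes there were at 28.8 CPM for Abcc9, 12.42 for Ccm2l, 15.75 for Flt4, 101.2 for Ly6a, 52.53 for Mgp and 288.1 for Slc2a1. Immune and glial genes there were at 27.8 CPM for A2m, 15.77 for Capg, 27.52 for Cebpd, 19.09 for Emp1, 11.07 for H2-Ab1, 10 for Lcn2, 38.92 for Lyz2, 16.06 for Osmr, 5.188 for S100a9 and 55.76 for Ube2l6. In replicate 3 of that group Aplnr was at 4.514 CPM and Pdcd10 at 14.73, and in replicate 2 Ccnf was at 3.406 and Steap3 at 6.83.

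The knockout effect differed between oxygen levels for 26 lists by camera with the preset correlation and for none with an estimated one. Median log2 differences with all libraries and then without KO hypoxia replicate 1 were, for immune lists, 1.339 and 0.976 for neutrophils and monocytes, 0.816 and 0.482 for border macrophages, 0.45 and 0.305 for antigen presentation, 0.446 and 0.294 for cytokines, 0.396 and 0.21 for complement, 0.289 and 0.208 for disease-associated microglia and 0.216 and 0.154 for homeostatic microglia. They were 1.037 and 0.265 for erythroid cells, 0.308 and 0.169 for iron and heme handling, 0.563 and 0.337 for reactive astrocytes, 0.568 and 0.408 for cell cycle, 0.42 and 0.408 for choroid plexus, 0.239 and 0.221 for myelin and 0.228 and 0.236 for glucocorticoid response. Vascular and matrix lists were at 0.469 and 0.294 for extracellular matrix, 0.368 and 0.21 for endothelial-to-mesenchymal transition, 0.358 and 0.239 for fibroblasts, 0.305 and 0.202 for smooth muscle, 0.28 and 0.185 for coagulation, 0.25 and 0.152 for tip cells and 0.19 and 0.067 for the KLF2 and KLF4 axis. The lists with a negative difference, where KO over flox was lower in hypoxia than in normoxia, were at -0.43 and -0.445 for striatum, -0.12 and -0.133 for mitochondrially encoded transcripts, -0.113 and -0.126 for glutamatergic neurons, -0.091 and -0.077 for synapse and -0.071 and -0.048 for cholesterol synthesis. The sign of a difference does not tell where the effect was larger: for choroid plexus, KO against flox was at -0.707 in normoxia and -0.122 in hypoxia. Without that library 3 of the 26 lists were no longer called: erythroid cells (adjusted p = 0.27), the KLF2 and KLF4 axis (0.29) and cholesterol synthesis (0.12). Choroid plexus was at 0.061 (adjusted p = 0.76) without KO normoxia replicate 2, where Ttr was at 1.95 CPM. Some members of the neutrophil and border macrophage lists had low levels in flox and KO hypoxia, such as Plac8 (0.0368 and 0.678 CPM) and Cbr2 (0.342 and 1.07). Others were higher, such as Csf3r (5.47 and 8.56) and Mrc1 (3.54 and 8.10). Whether such cells entered the tissue was not tested.

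Xist was at 793.2 CPM in flox normoxia replicate 3, 739.6 in KO normoxia replicate 3, 688.2 in KO hypoxia replicate 3 and 564.2 in KO hypoxia replicate 4, and at most 0.425 in the other 9 libraries. The summed CPM of Ddx3y, Uty, Kdm5d and Eif2s3y was at most 0.0145 in these 4 and at least 143 in the other 9, so the 4 may come from females. RNA of a female mixed into male libraries was argued against, since the Y-linked sum was at most 0.0102% of the lowest of the other 9. The mix of sexes as the source of the calls of KO against flox in hypoxia was argued against for the higher genes, of which 1240 of 1526 were kept with a sex term. It could not be settled for the lower genes, of which 229 of 513 were kept, all 513 with their sign (median log2 fold change -0.20 with median SE 0.052 before and -0.20 with 0.057 after), and whether labels or animals were exchanged was not tested.

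Among other splits of the libraries into groups of the same sizes, 1 of 35, the real one, gave as many as 2039 genes for KO against flox in hypoxia, and the highest other gave 1573, which set KO replicates 1, 3 and 4 apart from KO replicate 2 and the flox libraries. Ranking first is the most that 35 splits can show, and the split counts were not adjusted for one another. Chance was thus made less likely for the count of genes but was not excluded. It was not excluded for the 34 lists either, since 3 of 35 splits gave as many (highest other 34). For hypoxia in KO, 2 of 35 splits gave at least 202 genes, the other (213) setting KO hypoxia replicates 1, 3 and 4 apart, so chance was not excluded. The 35 lists were reached by 1 of 35 splits (highest other 33), but the counts lie close together and no list passed with an estimated correlation, so chance is left open for them. For the interaction, 60 of 60 splits gave at least 0 genes (highest other 8), as any split must, so this count tests nothing, and 14 of 60 gave at least 26 lists (highest other 32), so chance was not excluded for the lists. The 10 splits of 3 against 3 are too few for a share under 0.05: in normoxia KO against flox gave 524 genes (highest other 16; 1 split as large) and 28 lists (highest other 30; 3 as large), and hypoxia in flox gave 5 genes (highest other 0; 1 as large) and 18 lists (highest other 14; 1 as large).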

How the results depend on the processing

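The sex term and the fit to the 9 libraries with Y-linked transcripts were chosen after the data were seen. For KO against flox in normoxia the count of 524 genes was 995 with no filter, 839 by DESeq2, 249 and 333 by limma on log2(RPKM + 1) and log2(RPKM + 0.1), 106 by limma over genes with any RPKM, 311 in the 9 libraries and 250 to 397 with each library left out. In hypoxia the count of 2039 was 1241 by limma over any RPKM, 1030 with a fold of at least 1.5 as well and 1151 to 2490 with a library left out. For hypoxia in flox the count of 5 was 158 with no filter, 67 by DESeq2, 2 by limma with either pseudocount, 19 in a fit of only the libraries compared, 66 in the 9 libraries and 0 to 45 with a library left out. For hypoxia in KO the count of 202 was 833 with no filter, 749 by DESeq2, 46 and 42 by limma, 18 over any RPKM, 78 with the minimum fold, 30 in a fit of only the libraries compared, 94 in the 9 libraries and 2 to 463 with a library left out. The interaction called 55 genes with no filter, 8 by DESeq2, 2 by limma with either pseudocount, 4 over any RPKM, 10 in the 9 libraries and 0 or 1 with a library left out. With an estimated correlation 12, 16, 0, 0 and 0 lists passed in the order above, and fry called 0 lists for hypoxia in flox, 8 for hypoxia in KO and 0 for the interaction. With a library left out the lists numbered 24 to 32, 32 to 35, 14 to 21, 30 to 35 and 22 to 29. Fewer libraries were tested in the left-out fits, and for the other settings the cause was not tested.

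Same-numbered libraries did not deviate together (r between -0.137 and 0.127 over 12 pairs, 1 above 0.1), and 3 of 13 libraries matched best with their own number. The replicate block gave 510, 1571, 5 and 174 genes and 1 gene for the interaction. Over genes called in either comparison, the Pearson and Spearman values were 0.788 and 0.854 for the knockout effects and 0.605 and 0.774 for the hypoxia effects, and they describe genes chosen for their size.

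Of 290 named gene results, 126 kept direction and side of the threshold under every setting run. Those that changed sign had not passed the threshold. In the 9 libraries the log2 fold changes were -0.241 for Slco1c1 and 0.054 for Cx3cl1 (KO against flox, normoxia), 0.005 for Cx3cl1, -0.001 for Cx3cr1, -0.012 for Pdcd10, 0.015 for Gfap and -0.004 for Thbd (hypoxia in flox) and -0.099 for Gfap (hypoxia in KO). For the interaction they were 0.055 for Slco1c1, -0.113 for Gfap, -0.106 for Klf4, -0.441 for Klf2 and -0.073 for Vegfa. With the sex term Pdcd10 was at -0.003, Gfap at 0.067 and Thbd at -0.039 for hypoxia in flox, and Klf2 at -0.022 for the interaction. With a library left out, KO against flox in normoxia ran from -0.085 to 0.032 for Cx3cl1 and from -0.071 to 0.016 for Pdcd10. Hypoxia in flox ran from -0.111 to 0.006 for Cx3cl1, -0.01 to 0.054 for Pdcd10, -0.098 to 0.016 for Gfap and -0.092 to 0.125 for Thbd, and hypoxia in KO from -0.082 to 0.005 for Pdcd10. The interaction ran from -0.181 to 0.348 for Klf4, -0.278 to 0.28 for Klf2 and -0.083 to 0.126 for Vegfa. The mitochondrial share difference ran from -0.0538 to 0.241 (KO against flox, normoxia) and -0.117 to 0.273 (hypoxia in flox) percentage points. The top-50 share difference ran from -0.32 to 0.18 and -0.413 to 0.205 for KO against flox in normoxia and hypoxia, and from -0.255 to 0.235 and -0.347 to 0.27 for hypoxia in flox and KO.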

Other observations

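The genes and the tests in this part were chosen after their values had been seen. Bst1, an ectoenzyme of the bone marrow stroma, was at 0.205 ± 0.0661 CPM in flox and 3.70 ± 0.375 in KO in normoxia (SD, n = 3 each), and at 0.103 ± 0.0611 in flox (n = 3) and 7.94 ± 3.85 in KO (n = 4) in hypoxia, with log2 fold changes of 4.18 ± 0.40 and 6.19 ± 0.44 (SE). Igfbpl1, an IGF-binding protein relative, went the other way, from 2.35 ± 0.16 to 0.304 ± 0.181 CPM in normoxia and from 1.54 ± 0.12 to 0.399 ± 0.0946 in hypoxia. Bst1 in flox hypoxia lay near the floor of 3 counts (at most 0.0713 CPM), so the size of its fold there is uncertain. The interaction called 0 genes by edgeR, so a larger rise of Bst1 in hypoxia is not shown. Ttr, a choroid plexus transcript, was at 1.95 CPM in KO normoxia replicate 2, and between 274.1 and 461.7 CPM in the other 12 libraries. Gh was at 0.733 to 1.10 CPM in the flox hypoxia libraries and at most 0.036 in the KO hypoxia libraries.

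Endothelial lists rose together, so the KLF2 and KLF4, tip cell and barrier scores (mean log2 CPM) were also set against the pan-endothelial score of the same library. Relative to it, KO minus flox was -0.34, -0.567 and -0.47 in normoxia and -0.105, -0.425 and -0.594 in hypoxia. List genes that stay level in whole tissue pull these values down when endothelial markers rise, so the values do not show a loss per endothelial cell. The smallest adjusted p of 12 exact two-sided permutation tests was 0.114. With 3 against 3 libraries no p can be under 0.1, and with 3 against 4 none under 0.0286, which the tip cell and barrier scores reached in hypoxia, so missing the threshold does not show that the genotypes were equal.

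Clock genes that peak with Dbp and those in antiphase differed by 0.199 in flox and 0.414 in KO for hypoxia against normoxia (difference of median log2 fold changes, 11 and 5 genes). Collection at different times of day and an action of hypoxia on the clock may each give this, and with no collection time in the labels they cannot be told apart at 0.199. Between genotypes in normoxia the same difference was -0.282. Neuronal activity around collection was read from immediate early genes, which were 0.721 higher in hypoxia. It was tested on Dbp, Tef, Hlf, Nr1d2 and Ciart only, which were 0.333 higher. The list of 11 genes had smaller medians, 0.166 in flox and 0.26 in KO. The within-group relation to immediate early genes gave a shift of at most 0.048 for the tested genes. A slope fitted within such small groups is uncertain, so neuronal activity could not be excluded as a source.

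Gm6614, a predicted gene beside the Slco1c1 locus, had 9 counts in all flox libraries together and 2.91 to 8.25 CPM in each KO library, with log2 fold changes of 7.09 ± 0.57 and 7.12 ± 0.53. Extra copies of the Slco1c1 region on the Cre transgene could not be judged. The median over 4 genes there, Slco1c1 among them, was 0.146, but in normoxia they ran from -0.748 for Slco1b2 to 0.577 for Slco1a4. The threshold set for that median was too high to detect a small gain in copies, and a copy of part of the region may also remain. Reads of Slco1a4 counted on Gm6614 were argued against, as the ratio of Gm6614 to Slco1a4 was 104 times higher in KO. More endothelial RNA was argued against, since no pan-endothelial marker exceeded 2.322. A response to the knockout and a local effect of the inserted transgene were not separated, because each KO library carries both.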
